A study of Homo sapiens with 4 samples.

How the data were processed

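Total RNA of MCF-7 and MCF-7/Twist cells, both untreated per the labels, was labelled with Cy3 and hybridised to Agilent human miRNA arrays, 1 array per sample and 2 samples per cell line. The label of each sample gave its cell line and replicate number. The authors deposited 1 scanner file per array with spot intensity values, and a value table of 556 features. Per the file headers and the submitters' processing notes, the intensity values were made with Agilent Feature Extraction 9.5.3.1, with background subtraction and spatial detrending on, multiplicative detrending off and outlier spots marked. Per the file headers the array's annotation is on genome build hg18, and every position given is the target position listed there, 1 locus per miRNA even where several loci encode the same mature miRNA (miR-29b, miR-9 and let-7a among them). The deposited value table was equal to the scanner files' total gene signal on every array (maximum difference 0), so it is linear, uncentred and unscaled between arrays, and its column medians were −0.48, −0.51, −0.72 and −1.05. RNA extraction and labelling were done by a core facility per the labels, with no further detail.

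All 4 arrays were on 1 slide and in 1 scan, so slide and scan could not differ between the lines. The position of the arrays on the slide followed the cell line, so position and line cannot be told apart. Each array had 12033 spots, of which 11080 were not controls, for 1510 probes of 534 miRNAs, with 1 to 4 probes per miRNA and 5 to 40 spots per probe. The outlier spots left out were 2.25% to 2.79% per array.

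The processed signal, already background-subtracted, was averaged over the spots of a probe. A probe counted as well above background on an array where over 50% of its spots had the scanner software's flag, which the file headers set at 13 SDs of the background. Each array was divided by its 75th percentile over the 226 probes well above background on all arrays and multiplied by the geometric mean of the 4 percentiles. The scaled signals of a miRNA's probes were summed, values under a common floor of 19.8 were set to it, and log2 was taken (floor 4.31). The floor was the highest, over arrays, of the lowest probe signal well above background. A miRNA was tested if at least 1 probe was well above background on both arrays of at least 1 line, which left 154 miRNAs, 151 human and 3 viral, of which 113 were above background on all arrays. The floor understates changes of dim miRNAs and removes the spread of values held at it, so the SE of a miRNA at the floor in 1 line is too small; 4 tested miRNAs lay at the floor on all arrays. Of 110 called miRNAs with 2 or more probes above background, 0 had a probe of opposite sign. Probe signals were held at the same floor, so a probe under it in both lines had a change of 0 and could not be opposite. This held for all 3 such probes of miR-155, so the count says little about dim miRNAs.

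The lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0), as MCF-7/Twist minus MCF-7 with the cell line as the only term, two-sided, with Benjamini-Hochberg adjustment over the tested miRNAs and an adjusted p threshold of 0.05. The moderated variances had 3.09 degrees of freedom. An exact two-sided permutation test of 2 against 2 arrays cannot go below p = 0.333, so no single miRNA was tested that way. A miRNA well above background on both arrays of 1 line and on neither of the other has only a bound in the dim line. There, per array and probe, the higher of the lowest signal among probes well above background and the probe's own signal was summed over the miRNA's probes, and the bright line's mean over this value, from means of log2 values, is given as at least N-fold. No fold is given where this is under 1. In all, 25 miRNAs were above background only in MCF-7/Twist and 9 only in MCF-7, and for 6 and 8 of them the bound reached 2-fold.

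Lists of miRNA families, clusters, breast cancer classes and markers of other cell types were fixed before the data were examined, as were the tests of the comparison and of the lists, the rule for naming miRNAs and the alternatives, except the scaling by control features, which was chosen after seeing the data. The rule took, among calls whose values did not overlap between the lines, the 12 largest changes in each direction, up to 4 examples per list by size of change, and the 5 brightest miRNAs per line; list members outside it are named where a count had to be resolved. Lists with at least 3 tested members were tested with camera against the other tested miRNAs, with a preset correlation of 0.01, and adjusted over 17 lists. Of these, 2 were called, and 0 with an estimated correlation. That setting gave no list an adjusted p under 0.646. Even the miR-34 and miR-449 list, with an estimated correlation of −0.42, went from 0.109 to 0.646. A call lost there therefore does not show that correlation among the members undid it. The lists hold miRNAs of similar sequence (let-7, miR-200, miR-29, miR-17/20/106, miR-99/100, miR-130 and miR-34), which may share probe signal by cross-hybridisation, so single members of a family are uncertain. Names are those of the array's design, with the hsa- prefix left out. Names of host genes were taken from a gene table of assembly GRCh38.p14, in which 456 of the 470 human miRNAs had a hairpin gene of that name; whether a miRNA is exonic or intronic was not determined.

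Replicates were compared before averaging. The share of 113 miRNAs that differed between replicates beyond the 95% range of spot noise was 34.5% in MCF-7 and 72.6% in MCF-7/Twist (5% if they differed by noise alone), so neither pair was 1 array deposited as 2 samples. Spot noise within an array leaves out variation between hybridisations, so this comparison does not tell repeat arrays of 1 RNA from separate cultures; the replicates were counted as separate on the series' design text. The alternatives were 5 other scalings (1 of them by control features), normexp background correction with an offset of 50, other probe summaries, the deposited table, other filters and floors, outlier spots kept, other variance models, the replicate number as a block, and each array left out in turn.

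The procedure was tested on simulated data made from these arrays for the comparison of MCF-7/Twist with MCF-7, in 10 simulations with a median of 107.5 miRNAs tested. Planted log2 changes of 0.5, 1 and 2 were called in the right direction in 78.5%, 96.2% and 98.4% of cases. Of unchanged miRNAs 21.3% were called, but 3.30% when the true array gains were used in place of the estimated scaling, so most of this excess came from error in the scaling. None of the 545 unchanged cases was called with at least a 2-fold change (0 false calls of that size). The planted rises and falls were balanced in number, so this does not cover an unbalanced change between the lines. A shift planted alike in all members of the miR-17-92 list, with 13 members the largest tested, was called in 10 of 10 simulations. The 10 simulations without a planted shift gave 2 list calls in all. Simulated noise was independent between miRNAs, whereas the called miR-200 and basal-like or mesenchymal lists had estimated correlations of 0.20 and 0.59. These simulations therefore do not vouch for the calls of those lists, with 5 and 7 tested members. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3.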

Results

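MicroRNAs (miRNAs) were profiled in MCF-7, an oestrogen receptor-positive luminal breast cancer cell line, and in MCF-7/Twist, a derivative that the series title describes as overexpressing Twist, a transcription factor linked to epithelial-mesenchymal transition. Each line was represented by 2 biological replicates, according to the series' design text, and each replicate was hybridised to 1 one-colour Agilent array, giving 4 arrays. The arrays carried probes for 470 human and 64 viral miRNAs. On the MCF-7 arrays 124 and 132 miRNAs were well above background, and on the MCF-7/Twist arrays 143 and 151. No spot was saturated. The 75th percentile of the probes well above background on all arrays was 179 and 217 intensity units in MCF-7 and 309 and 369 in MCF-7/Twist before scaling, a 1.71-fold difference that scaling removed. Across the tested miRNAs, which are not independent replicates, log2 levels correlated with r = 0.999 between the MCF-7 replicates, 0.997 between the MCF-7/Twist replicates and 0.682 to 0.687 between the lines. The number of arrays, 2 per line, limits the precision of every value. No vector-transfected control line was analysed here, and a miRNA array does not measure TWIST1 mRNA, so the label of the MCF-7/Twist arrays could not be checked against the transgene.

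The comparison addressed which miRNAs differ between MCF-7 cells and the derivative overexpressing Twist. In MCF-7/Twist all 5 members of the miR-200 family, together with miR-203 and miR-375, were no longer well above background, and miR-200c, among the 5 brightest miRNAs of MCF-7, was at least 196-fold lower (at least 114-fold without scaling). In the opposite direction, miR-31 and miR-130a were not well above background in MCF-7 and were at least 24.4-fold and 23.2-fold higher in MCF-7/Twist, and miR-222 rose by 4.66 ± 0.11 on the log2 scale (limma estimate ± SE, n = 2 arrays per line). miR-29a, measured in both lines, rose by 3.19 ± 0.05, and miR-29b rose from a log2 level of 7.62 ± 0.11 (SD, n = 2) to 10.72 ± 0.05. miR-21, the brightest miRNA of both lines and widely described as an oncogenic miRNA, had a log2 level of 13.65 ± 0.06 (SD, n = 2) in MCF-7 and 14.10 ± 0.01 in MCF-7/Twist (adjusted p = 0.00385). This difference was called with the other scalings except quantile normalization, which sets the brightest miRNA of each array to 1 value, and not without MCF-7/Twist replicate 1 (adjusted p = 0.0801) or replicate 2 (adjusted p = 0.0518).

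Of 154 miRNAs tested, 57 passed an adjusted p threshold of 0.05 with at least a 2-fold change. Of these, 28 were higher and 29 lower in MCF-7/Twist. Without the size criterion 125 miRNAs passed, 52 higher and 73 lower, and 29 did not pass. None of the 57 larger changes turned direction under 5 other scalings of the arrays, whereas 31 of the 125 calls did under at least 1 of them. All 31 were lower in MCF-7/Twist under the main scaling, by at most 0.77 on the log2 scale. Except for quantile normalization, these scalings raise all log2 fold changes measured above the floor in both lines almost alike, by at most about 0.78. By construction no such rise, and no such fall of at least 1, could then turn. For these miRNAs only quantile normalization tested the direction of the larger changes. With scaling by control features 7 calls passed the threshold in the opposite direction (let-7c, miR-24, miR-126, miR-148b, miR-188, miR-324-3p and miR-331), without scaling 2 did (miR-148b and miR-331) and with median scaling 1 did (miR-148b). The share of calls that were higher was 41.6% under the main scaling, 50.8% with the percentile over all probes, 53.6% with quantile normalization, 64.3% with median scaling, 69.4% with scaling by control features and 75.2% without scaling. The median log2 fold change of the tested miRNAs was −0.20, −0.03, −0.04, 0.21, 0.39 and 0.46 in the same order, so that small changes are relative to the scaling chosen. Leaving out MCF-7 replicate 2 reduced the calls from 125 to 76, and a floor multiplied by 4 reduced them to 78. With normexp background correction 31 calls of at least 2-fold were made, and 20 of the 125 calls had the opposite sign, of which miR-30b, miR-374 and miR-663 passed the threshold as lower. Among the 57 larger changes 8 had the opposite sign and did not pass. All 8 were dim miRNAs that were higher under the main setting (miR-10a, miR-155, miR-362, miR-500, miR-532, miR-550, miR-590 and miR-660). In simulations of this comparison 21.3% of unchanged miRNAs were called, but 0 with at least a 2-fold change. Planted rises and falls were balanced there and at most 2 on the log2 scale, and unchanged miRNAs had a median estimated size of 0.15. The simulations therefore do not vouch for the larger calls under an unbalanced change or another background correction.

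**Figure D1:**
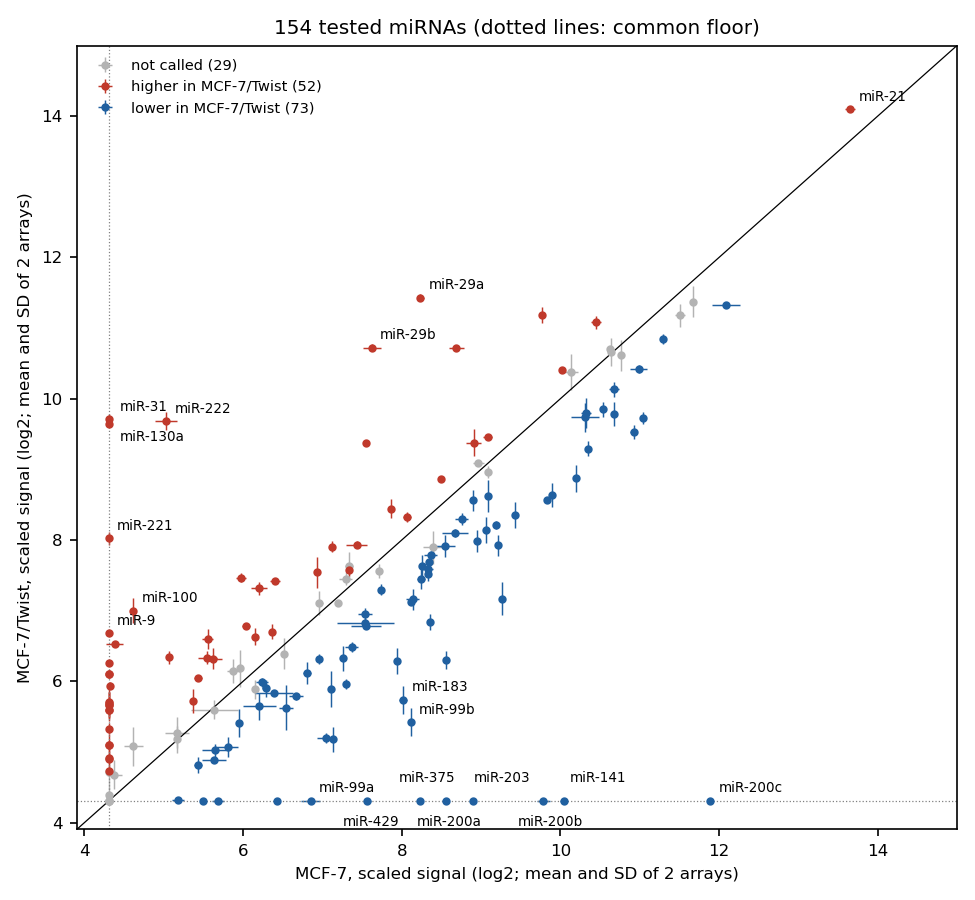
Mean log2 scaled signal of each of the 154 tested miRNAs in MCF-7 (horizontal axis) and MCF-7/Twist (vertical axis), with bars for the SD of 2 arrays, coloured by the limma call, and dotted lines at the common floor of 4.31. miR-200c, miR-141 and miR-200b lie far to the right on the floor of MCF-7/Twist, and miR-31, miR-130a and miR-221 lie high on the floor of MCF-7.

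The miR-200 family, which represses the transcription factors ZEB1 and ZEB2 and is a hallmark of epithelial cells, was lower as a whole. By camera with a preset correlation the family shifted down relative to the other tested miRNAs (adjusted p = 0.0175). With an estimated correlation, under which no list was called, this call was lost (adjusted p = 0.646). It was also lost without MCF-7/Twist replicate 1 (adjusted p = 0.0993) or replicate 2 (adjusted p = 0.0528). All 5 measured members fell, and all 5 were called when adjusted over the list alone. Each was well above background on both MCF-7 arrays and on neither MCF-7/Twist array, so that only a lower bound of each fold could be given. miR-200c (chromosome 12, 6943171 to 6943187, hg18) had a log2 level of 11.89 ± 0.02 (SD, n = 2) in MCF-7, and its neighbour miR-141 (6943584 to 6943600), with 10.04 ± 0.05, was at least 54.3-fold lower in MCF-7/Twist. Both genes lie within MIR200CHG in the gene table of assembly GRCh38.p14. From the chromosome 1 cluster, spanned by MIR200BHG, miR-200b (1092408 to 1092425) was at least 45.4-fold, miR-200a (1093163 to 1093180) at least 19.4-fold and miR-429 (1094302 to 1094319) at least 9.78-fold lower. Without scaling these bounds were at least 31.7-fold for miR-141, 26.5-fold for miR-200b, 11.3-fold for miR-200a and 5.71-fold for miR-429. limma's adjusted p ranged from 1.48e-05 for miR-200c to 4.91e-05 for miR-429.

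Among 9 other epithelial-enriched miRNAs on the array 6 were tested, of which 4 fell, 1 rose and 1 did not pass. The last, miR-96, was well above background on both MCF-7 arrays and 1 MCF-7/Twist array. It was held at the floor on all arrays, so its change could not be measured. When adjusted over the list alone 5 were called. miR-203, a miRNA of differentiating keratinocytes (chromosome 14, 103653563 to 103653580), was at least 24.7-fold lower, and miR-375 (chromosome 2, 219574614 to 219574628) at least 15.4-fold lower (14.4-fold and 8.997-fold without scaling). miR-183 and miR-182, neighbours on chromosome 7, were measured in both lines and fell by 2.28 ± 0.12 and 1.29 ± 0.09 on the log2 scale. The member that rose was miR-192, well above background only on the MCF-7/Twist arrays, and its level there was too low for a fold to be given. Camera did not call this list (adjusted p = 0.296), except without scaling (adjusted p = 0.0316). All 3 tested members of the luminal breast list were lower. Besides miR-375 these were miR-342, which fell by 1.64 ± 0.11, and miR-26a, which fell by 0.97 ± 0.05. miR-342 and miR-26a differed by −0.86 and only −0.20 without scaling. The shift of the luminal list did not pass (camera adjusted p = 0.120), and 3 members were called when adjusted over the list alone. It passed without scaling (adjusted p = 0.0364), with scaling by control features (adjusted p = 0.0473) and with no filter on dim miRNAs (adjusted p = 0.00182).

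The basal-like or mesenchymal breast list, made of miRNAs reported as more abundant in such breast tumours or lines, was shifted up by camera (adjusted p = 0.0225). This call was lost with median scaling (adjusted p = 0.0706) and with scaling by control features (adjusted p = 0.0780). It was also lost with an estimated correlation (adjusted p = 0.658), under which no list was called. Of 8 miRNAs on the array 7 were tested, 5 rose, none fell and 2 did not pass, with 5 called when adjusted over the list alone. Of the 2, miR-138 was well above background on both MCF-7/Twist arrays and on no MCF-7 array. Its summed signal was still under the floor on all arrays, so its change could not be measured. miR-31, whose gene lies within MIR31HG (chromosome 9, 21502156 to 21502172), had a log2 level of 9.71 ± 0.08 (SD, n = 2) in MCF-7/Twist. The neighbours miR-221 and miR-222 (chromosome X, 45490552 to 45490570 and 45491383 to 45491399, both within MIR222HG), which repress the cell cycle inhibitor p27, were both higher. miR-221 was at least 7.60-fold higher, and miR-222 was well above background on 1 of 2 MCF-7 arrays. miR-100 rose by 2.38 ± 0.11 on the log2 scale. The fifth was miR-155, not well above background in MCF-7 and too dim in MCF-7/Twist for a fold, and its direction turned with normexp background correction.

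Of 8 miRNAs reported to target ESR1, the gene of oestrogen receptor alpha, 6 were tested. miR-221, miR-222 and miR-22 rose, miR-193b fell by 1.25 ± 0.10 on the log2 scale, and 2 did not pass. Of the 2, miR-18b was well above background on both MCF-7/Twist arrays and on no MCF-7 array. Its summed signal was still under the floor on all arrays, so its change could not be measured. When adjusted over the list alone 4 were called. miR-22 (chromosome 17, 1563958 to 1563976, within MIR22HG) rose by 2.03 ± 0.06. The list as a whole was not called (camera adjusted p = 0.243). ESR1 itself is an mRNA and was not measured. Among 9 miRNAs reported as linked to Twist only 3 were tested. let-7i rose by 1.42 ± 0.07 and was among the 5 brightest miRNAs of MCF-7/Twist, and miR-10a, not well above background in MCF-7, was at least 1.48-fold higher but turned direction with normexp background correction. miR-424 differed by −0.15 ± 0.06 and did not pass (adjusted p = 0.117), and its sign turned under all 5 other scalings, past the threshold with median scaling, without scaling and with scaling by control features. miR-10b, miR-199a, miR-199a* and miR-214, also on this list, were not well above background on any array. The Twist-linked list did not pass (camera adjusted p = 0.344), with 2 members called when adjusted over the list alone.

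All 3 members of the miR-29 family, which represses collagens and DNA methyltransferases, were higher in MCF-7/Twist under every scaling, and all 3 were called when adjusted over the list alone. miR-29a (chromosome 7, 130212048 to 130212066) rose from a log2 level of 8.24 ± 0.04 to 11.43 ± 0.05 (SD, n = 2), which placed it among the 5 brightest miRNAs of that line. miR-29c rose by 1.62 ± 0.04 and was well above background on 1 of 2 MCF-7 arrays. The family's shift fell short of the threshold (camera adjusted p = 0.0574; 0.646 with an estimated correlation). It passed with normexp background correction (adjusted p = 0.00163), the mean of log2 probe signals (adjusted p = 0.0380), the brightest probe (adjusted p = 0.0403) and no filter on dim miRNAs (adjusted p = 0.000116). Of 5 miR-30 miRNAs 4 rose, led by miR-30a-5p with 1.81 ± 0.03, while miR-30e-5p did not pass and turned direction with quantile normalization. The smaller rises of miR-30b, miR-30c and miR-30d kept their direction under the other scalings and turned with normexp background correction. miR-30b was then called as lower (−0.42, adjusted p = 0.0218), whereas miR-30c and miR-30d did not pass (adjusted p = 0.413 and 0.783). All 3 tested members of the p53-induced miR-34 and miR-449 family were higher. miR-34b and miR-34c, neighbours on chromosome 11, were at least 2.69-fold and 1.41-fold higher, and miR-34a rose by 0.26 ± 0.06. Neither the miR-30 list nor that of miR-34 and miR-449 was called (camera adjusted p = 0.109 for both), except with no filter on dim miRNAs (adjusted p = 0.000566 and 0.00690), and 4 and 3 of their members were called when adjusted over the list alone.

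Several families split between loci. In the miR-99/100, let-7 and miR-125 clusters 5 of 7 members fell, 1 rose and 1 did not pass, with 6 called when adjusted over the list alone. The chromosome 19 neighbours miR-99b, let-7e and miR-125a fell by 2.69 ± 0.12, 1.32 ± 0.11 and 2.10 ± 0.14, and miR-99a on chromosome 21 was at least 3.98-fold lower (2.32-fold without scaling), whereas miR-100 on chromosome 11 rose. The remaining fall, that of let-7c, turned direction under 3 other scalings and was called as higher with scaling by control features (adjusted p = 0.0368). Of 5 miRNAs of the miR-23/24/27 clusters, miR-23a and miR-27a rose by 0.63 ± 0.07 and 0.38 ± 0.04. miR-23b and miR-27b fell by 1.39 ± 0.07 and 1.26 ± 0.03, and miR-24, encoded in both clusters, fell by 0.44 ± 0.05, a direction that turned under 3 other scalings, with a call as higher (0.26, adjusted p = 0.0106) with scaling by control features; all 5 were called when adjusted over the list alone. In the miR-130 and miR-301 family miR-130a (chromosome 11, 57165304 to 57165322, within MIR130AHG) and miR-130b rose. miR-301 fell by 1.21 ± 0.15, and the fall of miR-454-3p turned direction without scaling and with scaling by control features; 4 members were called when adjusted over the list alone. None of these lists was called as a whole (camera adjusted p = 0.399, 0.710 and 0.637).

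Among 13 miRNAs of the growth-promoting miR-17-92 cluster and its paralogues 6 rose, 3 fell and 4 did not pass. Of the 4, miR-18b, well above background only on the MCF-7/Twist arrays, was held at the floor on all arrays, so its change could not be measured. When adjusted over the list alone 9 were called. miR-363 was at least 2.00-fold higher and miR-19a rose by 0.61 ± 0.13, while miR-93 and miR-25 fell by 1.32 ± 0.06 and 0.89 ± 0.10, and the fall of miR-106b turned direction without scaling and with scaling by control features. miR-93 and miR-25 differed by −0.54 and only −0.12 without scaling. In the let-7 family, whose members repress RAS and HMGA2, let-7i rose, 5 of 10 members fell and 4 did not pass, with 3 called when adjusted over the list alone. let-7e and miR-98 (−0.93 ± 0.11) were lower under every scaling, whereas the falls of let-7c, let-7d and miR-202 turned direction under at least 1. The differences without scaling were −0.54 for let-7e and only −0.16 for miR-98. let-7a and let-7f, among the brightest miRNAs of MCF-7, differed by −0.30 ± 0.13 and −0.33 ± 0.10 and did not pass, and both passed as higher without scaling (adjusted p = 0.0224 and 0.0331) and with scaling by control features (adjusted p = 0.00586 and 0.00627). let-7g also did not pass, and its sign turned under all 5 other scalings. In the miR-15/16 family miR-15a rose by 0.58 ± 0.08, miR-195 fell by 0.88 ± 0.06 and 3 members did not pass, of which miR-15b and miR-424 turned direction under at least 4 other scalings and passed as higher without scaling and with scaling by control features, with 2 members called when adjusted over the list alone. miR-195 differed by only −0.11 without scaling. All 3 tested miR-181 members were lower and called when adjusted over the list alone, miR-181a by −0.88 ± 0.07, but miR-181b and miR-181d turned direction without scaling and with scaling by control features. miR-181a differed by only −0.10 without scaling. Camera called none of these lists (adjusted p = 0.296 for miR-17-92, 0.433 for let-7, 0.999 for miR-15/16 and 0.296 for miR-181). Of the Xq26 cluster list only miR-424 was tested.

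**Figure D2:**
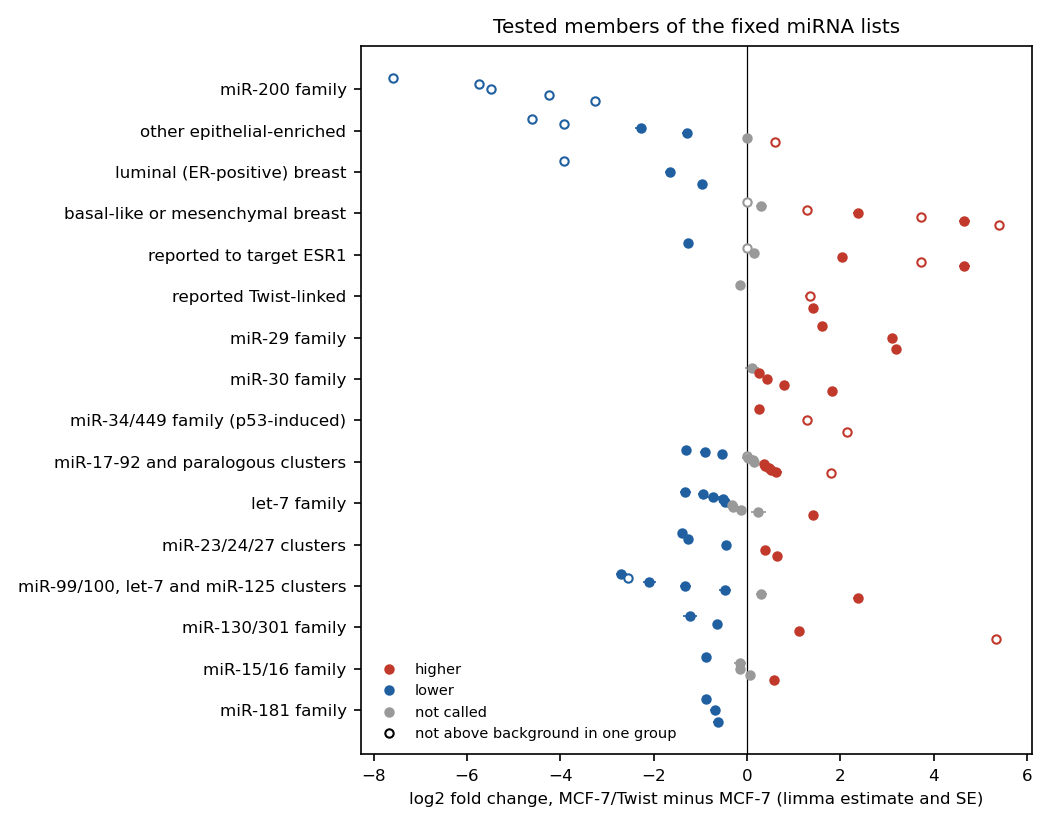
Log2 fold change, MCF-7/Twist minus MCF-7, of the tested members of 16 miRNA lists, with bars for limma's SE, on values held at the common floor. Open symbols mark miRNAs not well above background in 1 line, whose plotted change depends on the floor; the miR-200 family lies wholly to the left and the miR-29 family wholly to the right, and small falls of the let-7, miR-15/16, miR-17-92, miR-23/24/27, miR-130 and miR-301 and miR-181 members turn direction under some scalings.

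Other miRNAs were also among the 12 largest changes in a direction. miR-9 (chromosome 1, 154656808 to 154656827) and miR-140 (chromosome 16, 68524508 to 68524528, within WWP2) were not well above background in MCF-7 and were at least 1.99-fold and 2.23-fold higher in MCF-7/Twist. miR-652 (chromosome X, 109185276 to 109185295, within TMEM164) fell by 2.26 ± 0.08, and miR-345 (chromosome 14, 99843970 to 99843985) fell by 2.12 ± 0.03 to a level at the floor. miR-494, among the brightest in both lines, was lower by −0.77 ± 0.10, a direction that turned without scaling.

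Markers of cell types that the cultures should not hold were largely below background. None of 16 fibroblast or stromal, 7 blood cell, 6 muscle, 1 liver, 8 pluripotent stem cell or 44 placental chromosome 19 miRNAs was well above background on any array. Of 2 endothelial markers miR-126 was measured and was lower by −0.38 ± 0.08, which turned direction with median scaling, without scaling and with scaling by control features, the last with a call as higher (0.33, adjusted p = 0.00722). Of 6 neural markers miR-9 was higher, as given above, and miR-128a differed by 0.30 ± 0.13 and did not pass, but passed as higher with 4 other scalings and as lower with normexp background correction (−0.43, adjusted p = 0.0186). miR-9*, also a neural marker, was well above background on 1 MCF-7/Twist array and on no MCF-7 array, so it was not tested in the main setting. The neural list was called with no filter on dim miRNAs (camera adjusted p = 0.0370). Of 64 viral miRNAs, expected to be absent, 3 gave signal on all arrays. ebv-miR-BART13, ebv-miR-BART19 and kshv-miR-K12-3 were lower by −0.59 ± 0.07, −0.58 ± 0.07 and −0.55 ± 0.14, and all 3 turned direction without scaling and with scaling by control features. All 3 were called as lower among all tested miRNAs (limma adjusted p = 0.00621, 0.00512 and 0.0354) and when adjusted over the list alone. Falls of this size were thus called under the main scaling for miRNAs expected to be absent. Camera did not call the list (adjusted p = 0.308).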

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

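The scaling by control features named hur_, whose role is not given in the sources used here, was chosen after seeing the data; the other alternatives were fixed before. For 67 named miRNAs 22 alternatives gave 1454 values, of which 1278 kept direction and side of the threshold, 121 lost and 13 gained the threshold and 42 turned direction, called or not. Of the 57 calls of at least 2-fold, 54 to 57 remained called in the same direction under the other scalings. The slide or scan as a block was not run, since there was 1 slide and 1 scan. The deposited value table equals the total gene signal, so these 2 alternatives gave the same values. Which miRNAs were above background in 1 line only (34) did not change in number with the scanner software's own detection flag. The replicate block gave 120 calls, with 118 of the 125 calls kept; samples of the same number did not deviate together (correlation 0.02 across miRNAs), and the block changed neither list call. With signal near background, changes under the floor cannot be seen, and 41 of 154 tested miRNAs were not above background on every array.

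The number of miRNAs called was 125 and became 78 with the floor multiplied by 4, by construction, and 76 to 106 with 1 array left out (76 without MCF-7 replicate 2), where the lone array of a line is assumed to vary like the other line's. The number called with at least 2-fold change was 57 and became 31 with normexp, 29 with only miRNAs above background on all arrays, by construction, and 33 with the floor multiplied by 4. The share of calls higher was 41.6% and became 64.3% with median scaling, 53.6% with quantile normalization, 75.2% without scaling, 69.4% with the hur_ features, 19.5% with normexp and 30.8% with the floor multiplied by 4. The number of lists called was 2 and became 1 with median scaling, 4 without scaling (with the luminal list at adjusted p = 0.0364 and the other epithelial list at 0.0316), 7 with no filter on dim miRNAs (adding the luminal, miR-29, miR-30, neural, and miR-34 and miR-449 lists), 0 with only miRNAs above background on all arrays, 0 with an estimated correlation, and 1 to 2 with 1 array left out. For the miR-200 list the adjusted p was 0.646 with an estimated correlation and 0.00878 to 0.0993 with 1 array left out (over the threshold without either MCF-7/Twist array). For the basal-like or mesenchymal list it was 0.658 with an estimated correlation, 0.0706 with median scaling and 0.0780 with the hur_ features. The miR-29 list gained a call with normexp (0.00163), the mean of log2 probe signals (0.0380) and the brightest probe (0.0403), and the luminal list with the hur_ features (0.0473). With only miRNAs above background on all arrays 10 lists were tested. That filter removed all 5 miR-200 members and left the basal-like or mesenchymal list under 3 members. By construction, neither of these lists could then be called. Except where the construction is named, the cause was not tested.

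Among the named miRNAs, without scaling, which by construction adds about 0.78 to each log2 fold change above the floor, the sign turned for ebv-miR-BART13 (0.19), ebv-miR-BART19 (0.20), kshv-miR-K12-3 (0.22), let-7a (0.48), let-7f (0.45), miR-126 (0.40), miR-15b (0.63), miR-181b (0.16), miR-181d (0.082), miR-202 (0.058), miR-24 (0.33), miR-424 (0.63), miR-454-3p (0.13) and miR-494 (0.0099). Over all 125 calls the sign turned for 31 without scaling. Among the named miRNAs it turned with the hur_ features for ebv-miR-BART13 (0.12), ebv-miR-BART19 (0.13), kshv-miR-K12-3 (0.15), let-7a (0.40), let-7f (0.38), miR-126 (0.33), miR-15b (0.56), miR-181b (0.087), miR-181d (0.011), miR-24 (0.26), miR-424 (0.56) and miR-454-3p (0.063), with median scaling for let-7a (0.22), let-7f (0.20), miR-126 (0.14), miR-15b (0.38), miR-24 (0.082) and miR-424 (0.38), with quantile normalization for let-7a (0.15) and miR-424 (0.31), and with the percentile over all probes for miR-15b (0.073) and miR-424 (0.074). With normexp it turned for miR-10a (−0.025), miR-128a (−0.43), miR-30b (−0.42), miR-30c (−0.10) and miR-30d (−0.027), and 8 of the 57 larger calls and 20 of all 125 had the opposite sign. By construction, the normexp offset followed by scaling pushes dim miRNAs down in MCF-7/Twist. Calls that passed the threshold in the opposite direction numbered 7 with the hur_ features, 3 with normexp, 2 without scaling and 1 with median scaling. With 1 array left out miR-15b ranged from −0.31 to 0.0035. Except where the construction is named, the cause was not tested.

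The direction of 3 lists that were not called also turned, and none was called with the direction turned. For let-7 the adjusted p was then 0.708 with normexp and 0.898 with the hur_ features, and for miR-23/24/27 it was 0.598 with normexp. For miR-15/16 it was 0.705 with the percentile over all probes, 0.567 with median scaling, 0.778 with quantile normalization, 0.721 without scaling, 0.403 with normexp, 0.949 with the mean of log2 probe signals, 0.817 with the brightest probe, 0.743 with the total gene signal or the deposited table, 0.914 with only miRNAs above background on all arrays, 0.706 with the floor multiplied by 4, 0.989 with the replicate block and 0.688 with the hur_ features. With 1 array left out it was 0.887 to 0.944, and the direction turned only without MCF-7 replicate 2 (0.944) and without MCF-7/Twist replicate 2 (0.901). The cause was not tested.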

Other observations

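Several miRNAs outside the named set, chosen after their values were seen, also differed. In a cluster on chromosome X (49654518 to 49664625, hg18) miR-532, miR-362 and miR-500 were not well above background in MCF-7 and were at least 1.48-fold, 1.51-fold and 1.17-fold higher in MCF-7/Twist, and miR-660, above background on 1 of 2 MCF-7 arrays, rose by 1.79 ± 0.04 (log2, limma SE, n = 2 arrays per line). These 4 dim miRNAs had the opposite sign with normexp background correction, between −0.17 and −0.083, and then did not pass. From the same cluster miR-188 was lower by −0.44 ± 0.05, which turned direction under 3 other scalings and was called as higher with scaling by control features (adjusted p = 0.00818), and miR-501 differed by −0.04 ± 0.19 and did not pass. miR-210, known to be induced by hypoxia, rose by 1.49 ± 0.06. miR-484, miR-196a and miR-324-5p fell by 1.95 ± 0.11, 1.85 ± 0.08 and 1.51 ± 0.07. The chromosome 3 neighbours miR-191 and miR-425-5p fell by 0.98 ± 0.10 and 0.82 ± 0.06, and these 5 falls, like the rise of miR-210, kept their direction under every scaling. However, miR-191 and miR-425-5p differed by only −0.20 and −0.04 without scaling.

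In what follows, the 2 tests of neighbours with families left out and without scaling were chosen before their results were seen, and the others after. Neighbouring miRNAs, under 10 kb apart with hairpin arms left out, had log2 fold changes of the same sign, called or not, in 81.8% of 77 pairs. In 43 pairs both members were called, 39 of them in the same direction. Random reassignment of the fold changes gave a median of 46.8%, and none of 10000 reached the observed share (permutation p = 1e-04, the smallest they can give), which argues against chance. Without scaling the share was 88.3% (random median 58.4%, permutation p = 0.0005). Scaling shifts log2 fold changes above the floor almost alike wherever the miRNA lies, and the random reassignments carry the same shift. The share without scaling therefore cannot decide whether scaling was a cause, and no conclusion is drawn from it. With families left out the share was 76% of 50 pairs (random median 46%, permutation p = 0.0017). These pairs still include the miR-17-92 cluster on chromosome 13, where both arms of miR-17 and of miR-18a were each paired with other members. Without chromosome 13, families kept, the share was 72.5% of 51 pairs (random median 47.1%, permutation p = 0.0019). Leaving out both was not tested, so cross-hybridisation between similar sequences is not settled as a cause. Shared transcription of a cluster, or DNA copy number differing between the lines, may account for the shared direction of neighbours. Neither was measured, so each stays a hypothesis.

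The loss of miR-200 family, miR-203 and miR-375 signal in MCF-7/Twist was weighed against 3 explanations. Dimmer arrays or their scaling are argued against, since without scaling the smallest bound among these 7 miRNAs was still at least 5.71-fold. Whether the 5 miR-200 members were lost singly or share signal by cross-hybridisation cannot be told apart: miR-203 and miR-375, whose smaller bound was at least 15.4-fold, or 8.997-fold without scaling, were grouped with them because they had fallen. The arrays hold only 1 MCF-7/Twist line and no vector control, so an effect of Twist and the selection or drift of a clone cannot be told apart. A Twist effect on these miRNAs may therefore be put forward only as a hypothesis.

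Before scaling, the miRNA signal of the MCF-7/Twist arrays was 1.71-fold that of the MCF-7 arrays at the 75th percentile. Overall brightness of the scan is argued against by the bright corner feature, whose ratio was 0.998. Of the control features mr_1 had a ratio of 0.645 and hur_4 of 0.646, and the other 4 lay between 1.11 and 1.34, but what they measure is not given in the sources used here, so they do not decide whether more RNA of every kind was labelled. This, a larger miRNA share of the RNA in MCF-7/Twist and the position on the slide, which followed the cell line, stay open, and a true overall rise could mean that the smaller falls reported under the main scaling are not falls (miR-24, for example, had a log2 fold change of 0.33 without scaling, which did not pass).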
